A study of Mus musculus with 4 samples.

How the data were processed

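Single-cell RNA sequencing was performed on the stromal vascular fraction (SVF, the non-adipocyte cells released by digesting a fat pad) of mouse inguinal white adipose tissue (iWAT). Tissue came from 7 pooled control mice and 8 pooled mice of a line named iAdFASNKO in the labels, a name the labels do not spell out and which is known to stand for an inducible knockout of the fatty acid synthase gene Fasn in adipocytes. The submitters' design text names a strain for the control mice, and the genetic background of the pools was not compared. Each pool was split with magnetic beads into a lineage-marker-positive part (Lin+) and the remaining stromal part (Lin-). This gave 4 libraries, 1 for each genotype and fraction, made with a droplet kit that reads the 3' end of transcripts and counts unique molecular identifiers (UMIs).

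The deposited matrices hold raw UMI counts, 1 whole number per gene and barcode and not normalized, per the file headers and the values themselves. Cell Ranger 3.1.0, Seurat 3.0 and the genome build mm10 are named in the submitters' processing notes, while the matrix header gives software version 3.0.2. The annotation release and any filter on barcodes before deposit are not given in the sources used here. Each matrix holds the Lin+ and the Lin- library of 1 genotype, and the labels state which barcode tag belongs to which fraction. The genotype of each matrix was read from its name, which matches only 1 of the 2 treatments in the labels. A matrix under the wrong name would turn every direction between genotypes. Gene coordinates are those of the GENCODE M21 annotation of the same build, joined by gene identifier, and 31053 features were listed in both matrices.

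Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. The mitochondrial limit was exceeded by unequal parts of the libraries. In Lin+ these were 463 of 3686 control and 1327 of 6133 iAdFASNKO barcodes, and in Lin- 519 of 3661 and 330 of 4856. Doublets were called in each library with Scrublet (scanpy 1.11.5, expected rate 0.06), which marked 1.16% and 1.54% of the Lin+ cells (control, iAdFASNKO) and 0.935% and 2.22% of the Lin- cells. Under the stricter filter named later it marked 0.293% to 0.549%, so doublets were hardly removed there. In the main setting the called cells were removed, together with clusters of which over 50% of cells were called. The files held 18336 barcodes and 14675 cells were retained, where the labels speak of about 6000 cells aimed at per condition. Total UMIs ran from 21622291 (Lin+ control) to 33016494 (Lin- control), with 25865546 in the Lin+ and 22557680 in the Lin- iAdFASNKO library. Haemoglobin transcripts took 4.95% and 5.11% of the Lin+ UMIs.

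Counts were log-normalized, and all retained cells were clustered together on 2000 variable genes, 30 principal components and a graph of 20 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0). Proliferation, sex-linked, mitochondrial and antigen-receptor segment genes were kept out of the variable genes. Cells of myeloid clusters were clustered again with 20 components, which gave the clusters whose numbers start with M. A cluster was named "X-like" where at least 3 markers and 50% of the markers of class X were on, each detected in at least 20% of its cells and at 20% or more of its level in the highest cluster. It stayed unnamed where its 10 leading genes went against the name. Where haemoglobin or proliferation genes led a cluster, it stayed unnamed too. The markers, cell filter, clustering settings, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The thresholds of the naming rule and the second round of clustering for myeloid cells were set afterwards.

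Each genotype and fraction is 1 library of pooled mice, so no test between genotypes was run and no p-value is given. Raw counts were summed over the cells of a class in each library and expressed as CPM, counts scaled to a common total. Shares of cells carry Clopper-Pearson 95% intervals, ratios of shares Katz intervals, CPM values exact Poisson intervals and CPM ratios exact conditional binomial intervals. All these intervals, and the floor of 3 counts used for a count of 0, cover counting error only, not differences between cells, mice or preparations. A ratio is always iAdFASNKO over control within 1 fraction unless stated otherwise.

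A gene counted as measured with at least 20 UMIs over both libraries, and as higher or lower with a ratio of at least 1.5 or at most 1/1.5 and an interval without 1. A gene list is described by the median log2 CPM ratio of its measured members, with an interval from Poisson draws of the counts. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these libraries and is not a test. Named genes were the first 12 in each direction in macrophage-like, 10 in progenitor-like and 3 in every other compared class. They were ranked by the interval bound nearest 1, among genes of at least 50 CPM in the higher library. Mitochondrial, ribosomal protein, gene-model-only, receptor segment and sex-linked genes were left out, as were genes that differed as far in the other cells of the same libraries. Where the other fraction held at least 50 cells of the class in both libraries, the ratio also had to lie on the same side of 1 there. Other genes are members of the fixed lists, some of which are not reported here. Macrophage-like and progenitor-like cells were compared whatever their number, and other classes where both libraries of a pair held at least 100 cells. ILC2-like cells of Lin-, with 94 and 193 cells, fell below that number and are described only among the closing observations. The all-gene median moved by over 0.1 (log2) under TMM scaling in Lin+ progenitor-like cells (-0.15), in smooth muscle-like cells (0.11) and in ILC2-like cells (-0.13).

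The summing and ratio step was tested on simulated data. For macrophage-like cells, over 6248 simulated genes, 90% of genes raised 2-fold and 82% of those at 0.5-fold met the size rule, as did 2.89% of unchanged genes. At 1.5-fold this was 42% and at 0.667-fold 38%. For progenitor-like cells, over 12635 genes, 100% of the genes raised 2-fold met it, as did 22% of those raised 1.5-fold but 72% of those at 0.667-fold, whose CPM ratios in the simulation were 1.47 and 0.652. Of unchanged genes 0.917% did. The simulation drew Poisson counts around the summed profile of the control library and held no variation between cells or mice.

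Alternatives covered looser (200 genes, 20% mitochondrial) and stricter (1000 genes, 5% mitochondrial) cell filters, doublets kept, resolutions of 0.5 and 2, 3000 variable genes with 50 components, and separate clustering of the genotypes. They also covered classes from markers in each cell, other denominators, TMM scaling, scaling each cell to 10000 UMIs, the other fraction, and other UMI minimums. Proliferating cells were those with 2 or more UMIs of G2/M genes after thinning each cell to 2000 UMIs. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.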

Results

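The 4 libraries held stromal vascular cells of mouse inguinal fat from control and iAdFASNKO mice, each split into a Lin+ and a Lin- fraction, with 1 pooled library per genotype and fraction. The series title speaks of signalling from adipocytes to macrophages and of thermogenesis, so the cell makeup and the expression of macrophages and adipose progenitors were compared by genotype. The Lin+ control library had 3686 barcodes, of which 2888 were retained, with a median of 5359 UMIs per cell. The Lin+ iAdFASNKO library had 6133 barcodes, 4400 retained cells and a median of 3282 UMIs. In Lin- there were 3661 barcodes and 3074 cells for control, with a median of 9116 UMIs, and 4856 barcodes and 4313 cells for iAdFASNKO, with a median of 4150 UMIs. By library medians the iAdFASNKO libraries were thus the shallower ones per cell in both fractions. In Lin+ this did not hold for every class. Median UMIs were 3002 in control and 3739 in iAdFASNKO T-cell-like cells, and 2322 and 2503.5 in B-cell-like cells. They were 8526 and 6817 in progenitor-like and 4841.5 and 4086.5 in macrophage-like cells of Lin+. No difference between genotypes has a replicate check, and values below compare libraries, not conditions. A difference in genetic background between the pools could also set expression, which was not tested. Some named genes differed about as far in the other cells of the same libraries and are not specific to the class. Examples are Bc1 in smooth muscle-like cells, Gstp1 in T-cell-like cells and Wdr89 in both.

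Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547, mm10), which encodes fatty acid synthase, was lower in progenitor-like cells of the iAdFASNKO libraries. In Lin- it was at 44.4 CPM (41.7 to 47.3) in control and 28.6 CPM (25.7 to 31.7) in iAdFASNKO, a ratio of 0.644 (0.569 to 0.726), and in Lin+ the ratio was 0.598 (0.515 to 0.694). A Fasn UMI was seen in 32.4% and 13.6% of the Lin- progenitor-like cells, at median depths of 10420 and 5418 UMIs. In smooth muscle-like cells, at 8059 and 4373 UMIs, it was seen in 11.4% and 5.07%. The ratio was 0.864 (0.511 to 1.54) in T-cell-like, 0.716 (0.393 to 1.39) in B-cell-like, 0.750 (0.298 to 1.81) in endothelial-like and 0.792 (0.511 to 1.24) in smooth muscle-like cells, none told apart from 1 at this depth. Macrophage-like cells held 4 Fasn UMIs in control and 0 in iAdFASNKO, too few for a ratio. These values check nothing about the labels, since the deletion is in adipocytes, which the libraries lack, and 3' tags may lie outside the deleted part.

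The magnetic sort enriched immune-like cells as a whole in Lin+ in both genotypes but separated the lineages only in part. Immune-like cells made up 31.5% of Lin+ and 6.44% of Lin- control cells, a ratio of 4.89 (4.23 to 5.66), and 52.2% and 8.83% of iAdFASNKO cells, a ratio of 5.90 (5.34 to 6.53). Stromal-like cells were at 0.664 times their Lin- share in Lin+ for control and 0.407 times for iAdFASNKO. B-cell-like cells were 39.1 times (19.4 to 78.8) as frequent in Lin+ as in Lin- in control and 199 times (89.5 to 444) in iAdFASNKO. T-cell-like cells were 30.7 and 17.6 times as frequent in Lin+. Smooth muscle-like cells (0.0338 and 0.0127) and type 2 innate lymphoid (ILC2-like) cells (0.147 and 0.107) lay mostly in Lin-. Several other immune-like classes were little enriched in Lin+ or not at all. Type 1 dendritic-like cells were at 1.06 (0.533 to 2.12) and 0.446 times their Lin- share, and migratory dendritic-like cells at 1.49 and 0.343. Plasma-cell-like cells were at 1.47 and 1.02 and mast-cell-like cells at 1.60 and 1.24. Progenitor-like cells still made up 56.8% of the Lin+ control and 31.6% of the Lin+ iAdFASNKO library.

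In Lin+, macrophage-like cells were a smaller part, and B- and T-cell-like cells a larger part, of the iAdFASNKO library. Macrophage-like cells numbered 150 (5.19%, 4.41 to 6.07) in control and 66 (1.5%, 1.16 to 1.90) in iAdFASNKO, a ratio of 0.289 (0.217 to 0.384). B-cell-like cells were at 10.2% (9.10 to 11.3) and 27.7% (26.4 to 29.1), a ratio of 2.72 (2.42 to 3.07), and T-cell-like cells at 6.99% and 17.2%, a ratio of 2.46 (2.12 to 2.85). Natural killer (NK)-like cells were at 2.77% and 0.955%, a ratio of 0.345 (0.238 to 0.499). Conventional dendritic-like cells of type 2 were at 2.56% and 1.09%, a ratio of 0.426 (0.297 to 0.610), and those of type 1 had a ratio of 0.410 (0.186 to 0.903). Neutrophil-like cells, with a ratio of 0.887 (0.581 to 1.35), were not told apart, but were at 0.536 (0.353 to 0.814) among immune-like cells alone. Plasma-cell-like cells were at 0.623% and 0.591% and mast-cell-like cells at 0.623% and 0.545%.

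Among immune-like Lin+ cells alone, the macrophage-like share was 16.5% (14.1 to 19.1) in control and 2.88% (2.23 to 3.64) in iAdFASNKO, a ratio of 0.174 (0.132 to 0.231). Without B- and T-cell-like cells it was 6.27% and 2.72%, a ratio of 0.434 (0.327 to 0.577), a denominator chosen after the data were seen. With that denominator the ratio was 0.518 (0.358 to 0.749) for NK-like cells, 0.640 (0.447 to 0.916) for type 2 and 0.617 (0.280 to 1.36) for type 1 dendritic-like cells, the last an interval that holds 1. The Lin- libraries held no macrophage-like cells, which allows a share of up to 0.0976% and 0.0696%. Unnamed clusters held 8.59% of the Lin+ control and 13.2% of the Lin+ iAdFASNKO cells. Under the stricter cell filter the ratio of macrophage-like shares, Lin+, was 0.760 (0.441 to 1.31), an interval that holds 1. That filter left 37 control and 5 iAdFASNKO cells of the class in unnamed clusters. The sort and depth differences between the libraries, which were not alike in all classes, can also set shares, which was not tested.

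In Lin-, the iAdFASNKO library held a smaller part of progenitor-like cells and a larger part of smooth muscle- and endothelial-like cells. Progenitor-like cells numbered 2182 (71.0%, 69.3 to 72.6) in control and 2207 (51.2%, 49.7 to 52.7) in iAdFASNKO, a ratio of 0.721 (0.695 to 0.748). Pericyte- or smooth muscle-like cells were at 10.2% (9.20 to 11.4) and 21.5% (20.3 to 22.8), a ratio of 2.10 (1.86 to 2.36). Endothelial-like cells were at 4.0% (3.34 to 4.76) and 5.80% (5.12 to 6.54), a ratio of 1.45 (1.17 to 1.79). Lymphatic endothelial-like cells were at 1.17% and 1.48%. Unnamed clusters held 3.38% and 6.14%. The ratio of pericyte or smooth muscle-like shares, Lin-, was 1.30 under the looser and 6.50 under the stricter cell filter. In the main setting 519 of 3661 control and 330 of 4856 iAdFASNKO barcodes exceeded the mitochondrial limit, so the size of these share differences depends on the filter. The ratio of endothelial-like shares, Lin-, was 0.473 when the genotypes were clustered separately, the opposite direction.

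**Figure D1:**
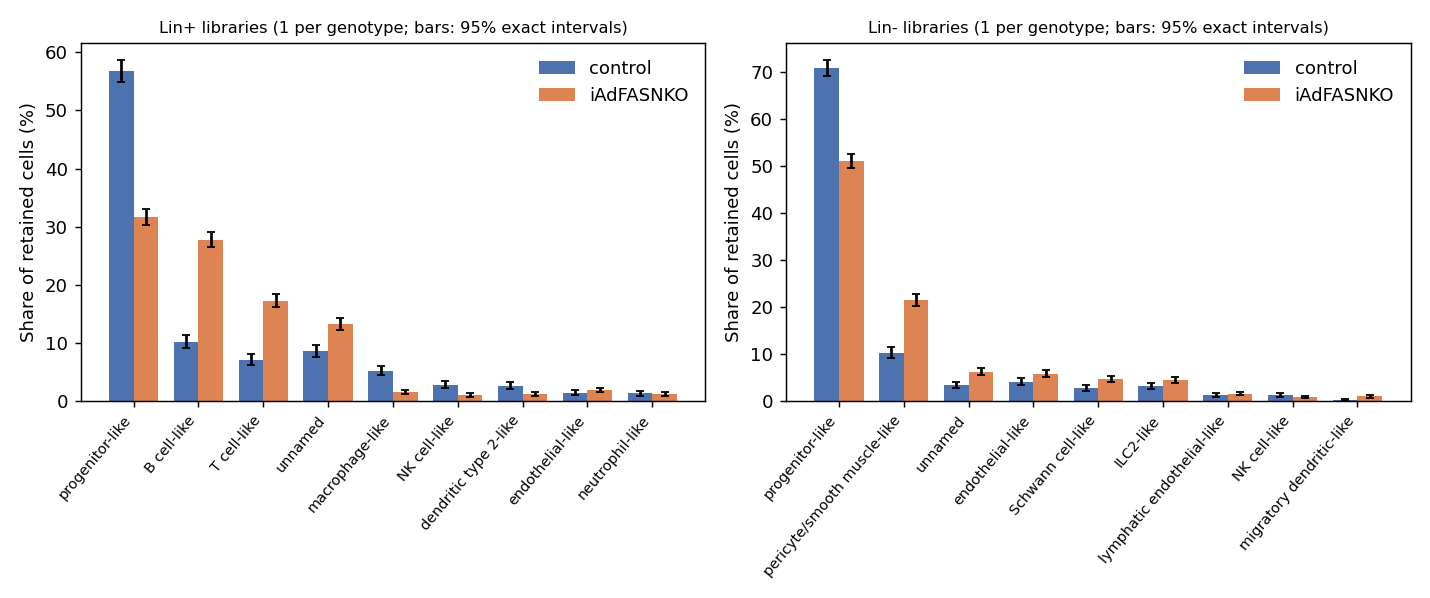
Share of retained cells (percent) of selected classes, and of all unnamed clusters together, in control and iAdFASNKO. Lin+ and Lin- libraries are in separate panels, with error bars giving 95% exact binomial intervals. Macrophage-like cells were at 5.19% and 1.5% of Lin+, and progenitor-like cells at 71.0% and 51.2% of Lin-.

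Summed over the class, macrophage-like cells of the Lin+ iAdFASNKO library had lower levels of lipid-associated, interferon response and classical activation genes. The median of their dissociation stress list was higher. Mgl2, a lectin of alternatively activated macrophages (chromosome 11, 70130329 to 70137550), was at 447 CPM in control and 1425 CPM in iAdFASNKO, a ratio of 3.19 (2.77 to 3.67). Klf4, a transcription factor (chromosome 4, 55527143 to 55532466), had a ratio of 3.17 (2.70 to 3.73). Ly6a, which encodes the surface protein Sca-1 (chromosome 15, 74994877 to 74998031), was at 737 and 57 CPM, a ratio of 0.0773 (0.0462 to 0.122). The cells numbered 150 and 66, with 787181 and 333417 UMIs in all and median depths of 4842 and 4087 UMIs. They came from the same 2 clusters in different proportions. Cluster M1, led by Cd209f, Ccl8 and Lyve1, held 48.7% of them in control and 68.2% in iAdFASNKO. Cluster M2, led by Rsad2, Fcgr1, Slfn4 and Plin2, held 51.3% and 31.8%. Genes that lead these clusters are among those named here. In M1 alone the lipid-associated, interferon response and classical activation medians lay nearer to 0. How far the mix of clusters sets the lower levels of the class was not tested.

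The classical activation list had a median log2 ratio of -0.78 (-1.15 to -0.47), with 1 of 14 measured members higher and 7 lower, below all 10000 matched random lists. Its size depended on the setting, as the median log2 of classical macrophage activation list, macrophage-like, Lin+, was -0.19 under the looser cell filter, -0.23 with no UMI minimum and -0.08 in cluster M1 alone, a choice made after the data were seen. The neutrophil-attracting chemokine Cxcl1 had 124 UMIs in control and 1 in iAdFASNKO, a ratio of 0.0190 (0.000478 to 0.108), while the log2 ratio of Cxcl1, macrophage-like, Lin+, moved from -5.71 to -0.82 under the looser filter. Its control UMIs lay in 11 cells, 31 of them in 1 cell, which the interval does not take into account. Cxcl2 had a ratio of 0.368 (0.318 to 0.424), Tnf 0.418 (0.234 to 0.705) and Ccl2 0.535 (0.404 to 0.702). Ccl4 was at 640 and 174 CPM, a ratio of 0.272 (0.203 to 0.357), and at 0.304 without the top cell of each library. In control 1 cell held 155 of its 504 UMIs. For Ccl5, 56 of the 75 control UMIs were in 1 cell, and the ratio was 0.0630 with all cells and 0.124 (0.00299 to 0.782) without the top cells. Il1b, at 1.08 (0.909 to 1.28), was not told apart, and Ptgs2 was higher, at 1.65 (1.22 to 2.23).

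The lipid-associated macrophage list had a median of -0.77 (-0.98 to -0.54), with 0 of 17 members higher and 9 lower, also below all random lists. It was smaller in other settings, where the median log2 of lipid-associated macrophage list, macrophage-like, Lin+, was -0.28 under the looser and -0.18 under the stricter cell filter and -0.18 in cluster M1. Osteopontin (Spp1) had 69 and 2 UMIs, a ratio of 0.0684, while the lipase Lpl had a ratio of 0.493 (0.383 to 0.629) and the lipid droplet protein Plin2 one of 0.483 (0.398 to 0.583). Lgals3 was at 0.502 (0.428 to 0.586), and Trem2, at 0.558 (0.280 to 1.03), was not told apart. The fatty acid binding protein Fabp5 was at 259 and 54.0 CPM, a ratio of 0.208 (0.121 to 0.338), but turned to the opposite direction under the looser filter and in cluster M1. The interferon response list had a median of -0.97 (-1.18 to -0.68), with 0 of 16 higher and 9 lower, and the median log2 of interferon response list, macrophage-like, Lin+, was -0.28 under the looser and -0.53 under the stricter filter. Its members Rsad2, at 252 and 42.0 CPM, Ifit1 and Isg15 had ratios of 0.167 (0.0896 to 0.287), 0.191 (0.0801 to 0.391) and 0.256 (0.162 to 0.387). Other lower genes were Slfn4, with a ratio of 0.0457 (0.00932 to 0.136), the transcription factor gene Egr3 (0.0605, 0.00720 to 0.226), Retnlg (0.143, 0.0605 to 0.290) and Tmem86a (0.120, 0.0241 to 0.368). The 78 control UMIs of Egr3 lay in 12 cells, 18 of them in 1 cell. Retnlg is a neutrophil marker in the fixed set. Its UMIs lay in 18 control and 2 iAdFASNKO cells, and its ratio was 2.58 in the other cells of the libraries. Il1rn was at 0.0968 (0.0309 to 0.232), with 55 of 122 control UMIs in 1 cell.

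The dissociation stress list of immediate early and heat shock genes had a median of 0.84 (0.73 to 0.91), with 13 of 18 higher and 0 lower, above all random lists. Jun was at 1413 and 3446 CPM, a ratio of 2.44 (2.24 to 2.65), Egr1 had 2.70 (2.38 to 3.07), Fosb 2.46 (2.15 to 2.81) and Fos 1.99 (1.81 to 2.18). The alternative activation list had a median of 0.17 (0.01 to 0.28), at the percentile of 82.7, with 7 of 26 higher and 1 lower. Without the top cell of each gene it was at -0.02, with 6 higher and 5 lower, a step that moved the median of all genes from -0.02 to -0.14, and the median log2 of alternative macrophage activation list, macrophage-like, Lin+, was -0.03 under the looser cell filter. Besides Mgl2 and Klf4, Cd163 was at 1.81 (1.51 to 2.16), Ccl8 at 1.94 (1.83 to 2.06) and Cd209d at 1.70 (1.41 to 2.06). The mannose receptor Mrc1 was at 1.27 (1.15 to 1.39) and Retnla at 0.712 (0.669 to 0.758). Egr2 was the lower member, at 0.308 (0.135 to 0.619). Arg1, which encodes arginase 1, had a ratio of 4.25 (2.40 to 7.75), but all 36 of its iAdFASNKO UMIs were in 1 cell. For Chil3, 27 of 64 UMIs were in 1 cell, with ratios of 2.91 (1.98 to 4.27) with and 1.94 (1.22 to 3.07) without the top cells.

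Other higher genes were Hp, at 47.0 and 153 CPM, a ratio of 3.25 (2.09 to 5.11) beside 2.67 in the other cells of the libraries, and Plac8, at 2.43 (2.0 to 2.95) and at 1.97 without the top cells, with 53 of its 219 UMIs in 1 cell. Both are monocyte markers in the fixed set, and how far monocytes within the class set these values was not tested. Single cells also held most UMIs of 3 more named genes. Gfod2 had 0 control UMIs and was at least 17.4-fold higher by the counting interval (22.8-fold against the floor of 3 counts), but 28 of its 29 UMIs were in 1 cell. H2-DMb2, a dendritic marker in the fixed set, had a ratio of 7.08 (2.69 to 21.8), and 3.31 (0.903 to 13.2) without the top cells, beside 4.38 in the other cells. Saa3 had a ratio of 3.67 (1.96 to 7.05), with 27 of 28 iAdFASNKO UMIs in 1 cell and all 18 control UMIs in another.

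The MHC class II list had a median of -0.11 (-0.16 to -0.03), with 0 of 8 higher and 1 lower, and the oxidative phosphorylation list one of 0.18 (0.05 to 0.30), with 0 of 24 members past the size rule. Each turned to the other side of 0 under 1 setting, as the median log2 of MHC class II list, macrophage-like, Lin+, was 0.0038 as a mean of scaled cells, and the median log2 of oxidative phosphorylation list, macrophage-like, Lin+, -0.20 with classes from markers in each cell. Stromal matrix transcripts, which other cells of the libraries held at high levels, were also lower in the iAdFASNKO macrophage-like cells. The extracellular matrix list had a median of -1.04 (-1.23 to -0.36), with 0 of 11 higher and 4 lower, namely Timp1, Sparc (0.358, 0.202 to 0.600), Col3a1 and Col1a1. The committed preadipocyte list was at -0.46 (-0.71 to -0.08), with 0 of 8 higher and 3 lower, but the median log2 of committed preadipocyte list, macrophage-like, Lin+, turned to 0.19 under the looser and 0.21 under the stricter filter and 0.056 in M1. Col1a1 was seen in 31.3% and 15.2% of these cells, beside 99.0% of Lin+ control progenitor-like cells, while the median log2 of extracellular matrix list, macrophage-like, Lin+, turned to 0.39 with classes from markers in each cell and 0.088 as a mean of scaled cells. Of the 3 measured members of the catecholamine handling list, 1 was higher and 0 lower. That member, monoamine oxidase A (Maoa), was at 26.7 and 69.0 CPM, a ratio of 2.59 (1.37 to 4.91). The proliferation list had a median of -1.66 (-2.20 to -0.75), with 0 of 6 higher and 3 lower, and of 0.08 without the top cell of each gene. In cluster M1 alone the median was -0.32 for the interferon, -0.03 for the alternative activation and 0.97 for the stress list. There the log2 ratio of Ly6a, macrophage-like, Lin+, was -3.55 and that of Mgl2 was 1.14. It was -1.09 for Slfn4, -1.14 for Rsad2 and -0.38 for Ccl4, nearer to 0 than in the whole class, and that of Fabp5 turned to 1.04, as it did to 0.88 under the looser filter, where 80 control and 25 iAdFASNKO cells of the class went unnamed.

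**Figure D2:**
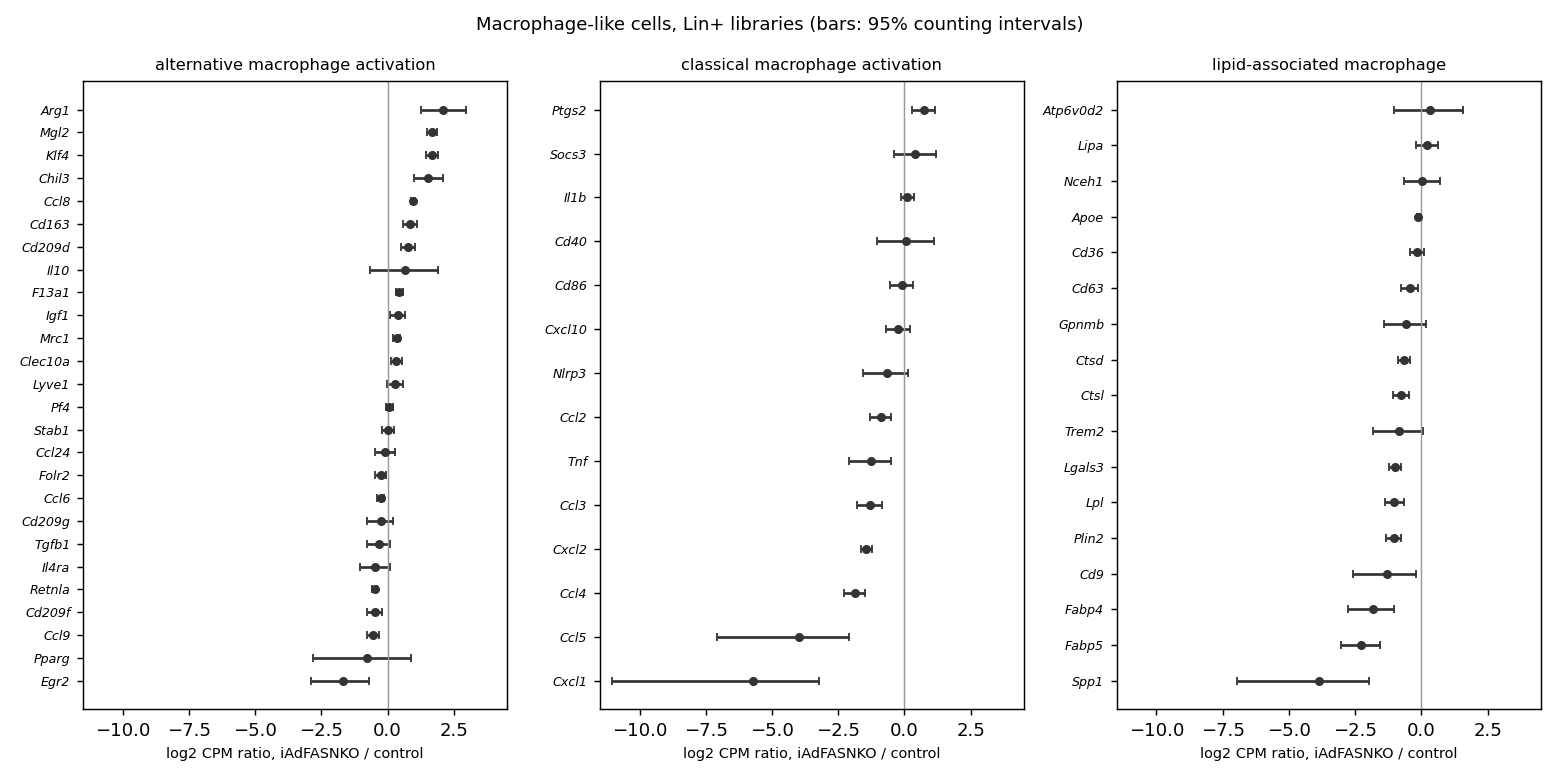
Log2 ratio of CPM (iAdFASNKO over control) of each measured member of the alternative activation, classical activation and lipid-associated lists in Lin+ macrophage-like cells, with bars giving 95% counting intervals. Members higher and lower numbered 7 and 1, 1 and 7, and 0 and 9. Without the top cell of each gene the alternative activation list had 6 higher and 5 lower and a median of -0.02, beside -0.14 for all genes.

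Few macrophage-like cells carried proliferation transcripts in either library. After thinning to 2000 UMIs, 2 of 127 control cells (1.57%, 0.191 to 5.57) and 0 of 54 iAdFASNKO cells, which allows up to 5.56%, had 2 or more UMIs of G2/M genes such as Mki67 and Top2a. Thinning left out 23 and 12 shallower cells, and without it 3 of 150 (2.0%) and 0 of 66 cells passed. In neutrophil-like cells, which do not divide, 0 of 13 and 1 of 20 thinned cells passed, at median depths of 1629 and 1839.5 UMIs before thinning. With classes from markers in each cell, a choice made after the data were seen, the shares were 1.60% (0.194 to 5.66) and 3.39% (0.413 to 11.7). A difference in either direction was not detectable at this depth.

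Progenitor-like cells of the Lin- iAdFASNKO library had higher levels of interstitial progenitor genes and lower levels of immediate early genes and of several chemokines. Akr1cl, an aldo-keto reductase family gene (chromosome 1, 65012689 to 65032759), was at 2.20 CPM in control and 56.4 CPM in iAdFASNKO, a ratio of 25.6 (19.2 to 34.9), beside 6.89 in the other cells of the libraries. Cdh11, which encodes cadherin-11 (chromosome 8, 102632095 to 102785642), was at 53.0 and 278 CPM, a ratio of 5.24 (4.91 to 5.60). The chemokine Cxcl14 (chromosome 13, 56288643 to 56296551) was at 1850 and 507 CPM, a ratio of 0.274 (0.267 to 0.281), beside 0.386 in the other cells. Cox8b, a cytochrome c oxidase subunit gene high in brown fat (chromosome 7, 140898945 to 140900446), was at 71.1 and 16.2 CPM, a ratio of 0.228 (0.197 to 0.264). The cells numbered 2182 and 2207. The largest cluster differed between the libraries. Cluster 5, led by Cxcl14, Smoc2, Cldn15 and Spry1, held 43.1% of the control and 6.98% of the iAdFASNKO cells, and cluster 2, led by Nrep, Cdh11, Lpl and Col4a1, 12.4% and 39.5%. Cdh11, Cxcl14, Cldn15 and Spry1 therefore both lead clusters and differ between the libraries.

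The other named genes that were higher were Emb (11.3, 9.53 to 13.5), Cmah (7.52, 6.33 to 8.99), the ferroxidase Heph (7.11, 6.04 to 8.42), Thbs4 (4.84, 4.16 to 5.64), Tmem176a (3.85), Wdr89 (3.46, 3.27 to 3.65, beside 2.70 in the other cells of the libraries), the growth factor Tgfb2 (3.46, 3.09 to 3.88) and complement C4b (3.13, 3.02 to 3.25). Those that were lower were Meox1 (0.297), Egr3 (0.313, 0.271 to 0.360), H2-Q10 (0.323, beside 0.351 in the other cells), Cldn15 (0.344), Spry1 (0.369), Adgre5 (0.373), the monocyte-attracting chemokine Ccl7 (0.384, 0.364 to 0.406) and Tubb4b (0.396). Sizes often differed in the Lin+ libraries of the same mice. Akr1cl was at 21.2 and Tgfb2 at 2.90 there, while Emb was at 2.28, Wdr89 at 1.54, C4b at 1.39 and Tmem176a at 1.19. Thbs4 was at 1.71 (0.795 to 3.76) in Lin+, on 14 and 17 UMIs, an interval that holds 1. In Lin- its UMIs lay in 17 control and 51 iAdFASNKO cells, with 77 of 236 and 89 of 657 in 1 cell each. Cox8b was at 0.0464 and Egr3 at 0.159 in Lin+, further from 1 than in Lin-, and Cxcl14, at 0.478, nearer to it.

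The interstitial progenitor list, of the Dpp4-positive cells of the connective tissue around fat lobules, had a median log2 ratio of 1.19 (0.94 to 1.28), with 7 of 10 members higher and 0 lower, above all random lists. Dpp4 was at 18.0 and 44.6 CPM, a ratio of 2.47 (2.17 to 2.82). Anxa3 had a ratio of 3.06 (2.86 to 3.27), Sema3c 2.90 (2.59 to 3.24) and fibronectin (Fn1) 1.80 (1.75 to 1.86), whereas Pi16 was at 1.13 (1.03 to 1.23). In Lin+ the list was at 0.72 (0.68 to 0.76), with 6 of 10 higher, and 43.3% and 59.8% of the progenitor-like cells there were in cluster 0, led by Pi16, Sema3c, Anxa3 and Dpp4. In Lin- that cluster held 39 and 56 cells, 1.79% and 2.54% of the progenitor-like ones. The dissociation stress list was at -0.61 (-0.64 to -0.58), with 0 of 18 higher and 10 lower, among them Fos (0.608) and Fosb (0.613), and at -0.63 in Lin+.

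The stromal chemokine and myeloid factor list had a median of -0.44 (-0.47 to -0.24), with 4 of 16 higher and 7 lower, and of 0.05 in Lin+. Besides Cxcl14 and Ccl7, Ccl2 was at 0.615, and the macrophage growth factor Il34 was at 20.1 and 4.84 CPM, a ratio of 0.241 (0.182 to 0.315), but of 0.979 (0.723 to 1.32) in Lin+. Cxcl12 was higher, at 1.57 (1.51 to 1.62), as was Saa3, at 3.72 (3.04 to 4.56), with 154 of its 310 iAdFASNKO and 88 of its 145 control UMIs in 1 cell each. The committed preadipocyte list was at 0.08 (0.07 to 0.10), with 4 of 12 higher and 2 lower, and at -0.69 in Lin+, with 1 higher and 7 lower. Apoe was at 2.92 (2.84 to 3.00) and at 2.02 in Lin+, whereas Fabp4 was at 1.73 (1.69 to 1.77) but at 0.419 in Lin+. The adipogenic regulator Pparg was lower in both, at 0.602 (0.524 to 0.689) and 0.360.

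Of the remaining lists, classical macrophage activation was at -0.47 (-0.52 to -0.35), with 2 of 9 measured members higher and 4 lower. The proliferation list was at 0.43 (0.17 to 0.65), with 3 of 11 higher and 0 lower. The MHC class II list was at 0.50 (0.04 to 0.95), with 2 of 6 higher and 0 lower. Without the top cells they were at -0.27, 0.42 and 0.31, and in Lin+ at -0.26, 0.19 and 0.62. The cell filters and other settings were not tried on them. The lists that follow lay closer to 0 in Lin-. The extracellular matrix list was at 0.10, with 5 of 22 higher and 1 lower, and at -0.15 in Lin+. Its higher members included Timp1 (2.70) and Col14a1 (2.35). The list of CD142-positive regulatory cells was at -0.12 (0.03 in Lin+), with F3 at 0.612 and Vit at 2.76. The oxidative phosphorylation list was at 0.06 (-0.19 in Lin+), with 0 of 24 members past the size rule, and the median log2 of oxidative phosphorylation list, fibroblast or adipose progenitor-like, Lin-, was -0.0046 with TMM scaling, which moved every gene of the class by -0.062, and -0.022 as a mean of scaled cells. The thermogenic list was at 0.08 (-0.14 to 0.32), with 1 of 8 higher and 2 lower, and at -0.37 in Lin+. Its higher member was Ppargc1a, at 2.07 (1.46 to 2.96). The lipogenesis list, which contains Fasn, was at -0.08 (0.10 in Lin+), with 1 of 12 higher, Mlxipl at 2.96 (1.80 to 4.95), and 1 lower, Fasn. The neurotrophic list was at -0.01 (-0.46 in Lin+), with Nrg1 at 7.53 (3.03 to 22.4). The adipocyte-abundant list had 4 measured members and a median of 0.31 (0.09 to 0.51). Its member Cebpa was at 0.614 (0.539 to 0.699), and the median log2 of adipocyte abundant list, fibroblast or adipose progenitor-like, Lin-, turned to -0.17 for members with at least 100 UMIs. Without the top cells the list was at 0.052, with 1 higher and 1 lower. Car3, at 1.72, had 199 of 510 UMIs in 1 cell.

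**Figure D3:**
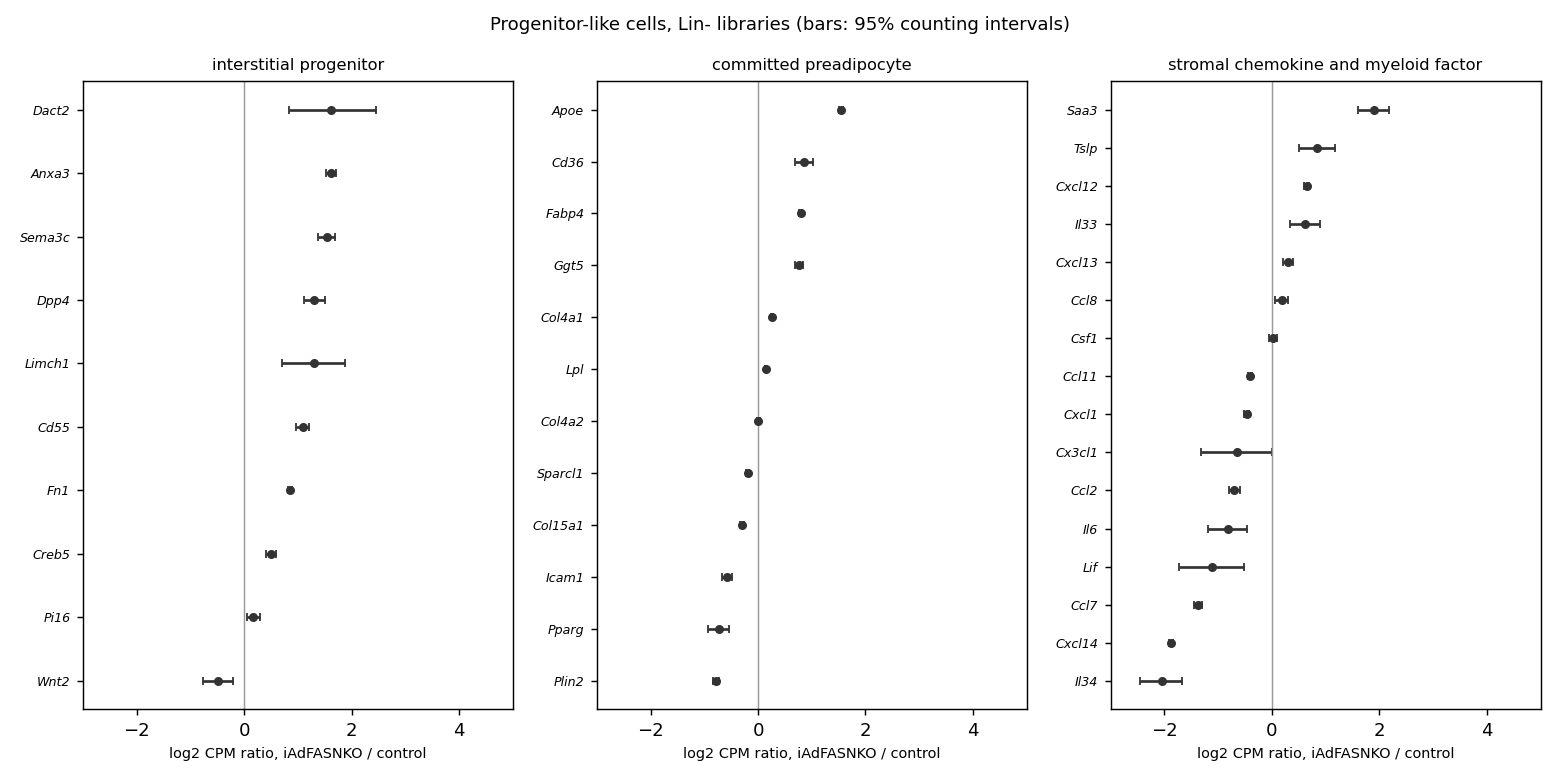
Log2 ratio of CPM (iAdFASNKO over control) of each measured member of the interstitial progenitor, committed preadipocyte and stromal chemokine lists in Lin- progenitor-like cells, with bars giving 95% counting intervals. Members higher and lower numbered 7 and 0, 4 and 2, and 4 and 7.

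In lymphocyte-like cells of the Lin+ iAdFASNKO library the median of the stress list was lower, with more members past the size rule in T- than in B-cell-like cells. In T-cell-like cells (202 and 756) the stress list was at -0.59 (-0.73 to -0.54), with 0 of 17 higher and 9 lower. Fosb had a ratio of 0.237 (0.181 to 0.311), the phosphatase gene Dusp5 one of 0.268 (0.201 to 0.357) and Gstp1, a glutathione transferase gene, one of 0.175 (0.106 to 0.287), beside 0.205 in the other cells of the libraries. The interferon response list was at 0.27 (0.15 to 0.74), with 3 of 15 higher, such as Ifit1 at 2.81 (1.43 to 6.29), and the naive lymphocyte list at 0.20 (0.03 to 0.30), with 1 of 9 higher. The higher named genes were Wdr89 (2.01, 1.73 to 2.33) and Ttn (6.32, 2.85 to 17.4), at 1.98 and 4.71 in the other cells of the libraries, and the collagen gene Col3a1 (2.28, 1.84 to 2.86). Of the iAdFASNKO UMIs, 69 of 183 for Ttn and 319 of 991 for Col3a1 were in 1 cell, and the log2 ratio of Col3a1, T cell-like, Lin+, was -3.62 under the stricter filter and -0.25 with doublets kept, the opposite direction. Stromal lists were also higher in T-cell-like cells, with extracellular matrix at 0.66 (0.36 to 0.89) and 8 of 19 higher, interstitial progenitor at 0.66 (0.19 to 1.00) and committed preadipocyte at 0.56 (0.071 to 1.12). Without the top cells they were at 0.12, 0.43 and -0.12, where the median of all genes was 0.12. The median log2 of extracellular matrix list, T cell-like, Lin+, was -0.32 under the looser and -2.26 under the stricter filter. The committed preadipocyte list also turned under both filters. With doublets kept, the committed preadipocyte and the interstitial progenitor list were on the other side of 0 as well. In B-cell-like cells (294 and 1220) the stress list was at -0.34 (-0.44 to -0.28), with 0 of 17 higher and 4 lower, namely Egr1 (0.445), Nr4a1 (0.488), Dusp1 (0.610) and Fos (0.638), while Fosb was at 1.19 (0.808 to 1.81). The interferon list was at 0.42 (0.07 to 0.75), with 2 of 15 higher and 1 lower, and the MHC class II list at 0.09 (0.01 to 0.12). Il4i1 had a ratio of 1.90 (1.28 to 2.94), beside 1.83 in the other cells, Pold4 1.54 (1.29 to 1.85) and Rbm3 1.47 (1.27 to 1.70). The matrix list was at -0.87 (-1.08 to -0.54), with 0 of 19 higher and 8 lower, and the committed preadipocyte list at -1.04, with 4 of 9 lower. Sparc, a stromal transcript, was at 0.261 (0.211 to 0.323), Hist1h2ap at 0.254, beside 0.389 and 0.373 in the other cells, and Slc15a2 at 0.240 (0.157 to 0.370). Under the stricter filter the log2 ratio of Sparc was 0.094, the median log2 of extracellular matrix list, B cell-like, Lin+, was 0.31 and the interferon list was at -0.086, all the opposite direction. The committed preadipocyte list turned under that filter too.

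Summed over the class, endothelial-like cells of the Lin- iAdFASNKO library (123 and 250 cells) had higher levels of activation and angiogenesis genes and metallothioneins. That list had a median of 1.10 (0.87 to 1.23), with 9 of 14 higher and 1 lower, above all random lists. The water channel Aqp1 had a ratio of 4.59 (4.04 to 5.23), the receptor Flt1 3.12 (2.43 to 4.05) and von Willebrand factor (Vwf) 3.01 (2.71 to 3.36), while Gpihbp1, which anchors lipoprotein lipase, was lower, at 0.439 (0.329 to 0.582). Mt2 was at 8.28 and 118 CPM, a ratio of 14.3 (7.94 to 28.2), Arl4d at 17.8 (7.35 to 56.4), and Mt1 at 7.52 (5.43 to 10.7), with 83 of 301 UMIs in 1 cell. With doublets kept the log2 ratio of Mt2, endothelial-like, Lin-, moved from 3.83 to 1.91. Ifi27l2a was at 0.268 (0.242 to 0.297) and Rgs16 at 0.326 (0.235 to 0.444). The proliferation list was at -1.18 (-1.57 to -0.85), with 0 of 11 higher and 6 lower, and at -0.39 without the top cells. For Cenpf (0.0426, 0.00858 to 0.129), 38 of 74 control UMIs were in 1 cell. The MHC class II list was at -0.75 (-0.97 to -0.36), with 2 of 6 lower, the interferon list at -0.37 (-0.65 to -0.25), with 5 of 15 lower, and the stress list at 0.01. The extracellular matrix list was at 0.36 (0.17 to 0.50), with 5 of 20 higher and 2 lower, and at 0.64 without the top cells, with 9 higher and 2 lower, but the median log2 of extracellular matrix list, endothelial-like, Lin-, was -0.27 with doublets kept. A cluster led by Aqp1, Vwf, Flt1 and Plvap held 9.76% of these cells in control and 33.6% in iAdFASNKO, so the genes that lead it overlap those named here. The other cluster, led by Cldn5, Clca3a1, Mmrn1 and Egfl7, held 90.2% and 66.4%. Mmrn1 is also a lymphatic endothelial marker in the fixed set. No values within these clusters were computed, so how far their mix sets the differences of the class was not tested.

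Smooth muscle-like cells of the Lin- iAdFASNKO library (315 and 927 cells) had lower levels of some heat shock and other stress genes. The stress list was at -0.47 (-0.54 to -0.42), with 0 of 18 higher and 6 lower, and the heat shock gene Hspa1a was at 1426 and 517 CPM, a ratio of 0.362 (0.344 to 0.382). The extracellular matrix list was at -0.41 (-0.58 to -0.34), with 2 of 21 higher and 9 lower, but at -0.24 without the top cells, with 2 higher and 3 lower. For Col3a1, 1 control cell held 473 of 1584 UMIs. The median log2 of extracellular matrix list, pericyte or smooth muscle-like, Lin-, was 0.04 under the looser and 0.29 under the stricter filter, the opposite direction. The oxidative phosphorylation list was at 0.29 (0.24 to 0.34), with 1 of 24 past the size rule, and Cox7c and Ndufa4 were at 1.46 and 1.44. The noncoding RNA Bc1 was at 121 and 979 CPM, a ratio of 8.06 (7.21 to 9.05), but was also at 7.26 in the other cells of the same libraries, and Wdr89 was at 3.41 (2.98 to 3.91) and 3.29. Mgp, at 2.76 (2.37 to 3.24), was at 1.52 without the top cells, with 456 of its 890 UMIs in 1 cell. Ifitm1 was at 0.257 (0.185 to 0.353) and Vtn, vitronectin, at 0.289 (0.211 to 0.391).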

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

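The tests of dilution, of haemoglobin-led cells, of markers in each cell, of handling, of free RNA, of cluster 0 and of a cluster mix as the whole cause were chosen only after the result was seen, while those of the looser cell filter and of the cluster mixes in general were set before.

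Macrophage-like cells were a smaller part of the Lin+ iAdFASNKO library, at 0.289 times the control share. A larger part of B- and T-cell-like cells did not account for all of it, since without them the ratio was 0.434 (0.327 to 0.577). Nor did the cell filter, at 0.458 (0.314 to 0.667) when looser and 0.403 (0.321 to 0.505) when looser with classes from markers in each cell, or haemoglobin-led myeloid cells counted as macrophage-like, at 0.368 (0.292 to 0.465). The stricter filter gave 0.760 (0.441 to 1.31), which holds 1, and naming may be part of that, since it left 37 control and 5 iAdFASNKO cells of the class unnamed, as the looser one did 80 and 25. A biological difference by genotype, an uneven yield of the sort and a lymph node kept in 1 of the pools remain open and were not tested.

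The median of immediate early and heat shock genes was higher in macrophage-like cells of the iAdFASNKO library and lower in its progenitor-, T- and B-cell-like cells. Handling that acts alike on all cells of the Lin+ sample would move these classes one way. The medians were 0.84 in macrophage-like cells and -0.63, -0.59 and -0.34 in the others, which argues against such handling as the only cause. Handling that acts differently by cell type cannot be judged this way. In Lin- the list was also lower in progenitor- (-0.61), smooth muscle- (-0.47) and ILC2-like cells (-0.68), and at 0.01 in endothelial-like cells. A mix of clusters M1 and M2 in other proportions was not the whole cause, since within M1 the median was 0.97 (0.86 to 1.11), with 13 of 18 higher and 0 lower. Within M2 it was 0.095 (-0.06 to 0.27) on 77 and 21 cells, so a difference there, and a part played by the mix, cannot be told apart. A response of macrophages to digestion that differs by genotype, and a biological difference in the tissue, may both be involved and were not tested.

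Interstitial progenitor genes were higher in Lin- progenitor-like cells of the iAdFASNKO library, with a list median of 1.19. Free RNA would raise them in other classes of the same libraries too, but the median was -0.11 (-0.42 to 0.23) in endothelial-like and -0.27 in smooth muscle-like cells, on 6 and 5 measured members. A mix of progenitor-like clusters was not the whole cause, since in 2 of 6 clusters the interval within the cluster lay above 0.2, at 0.62 (0.36 to 0.88) in cluster 3 and 1.78 (1.19 to 2.12) in cluster 8. Nor was a larger part of cluster 0, which interstitial genes led and which lay outside those 6, since it held 39 and 56 Lin- cells and the median without it was 1.44 (1.13 to 1.53). How far the mix contributes cannot be told apart from a difference within clusters, as the 6 medians had a middle value of 0.47, and more interstitial cells in other clusters or a difference by genotype, not tested, may underlie the pattern.

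Several lists moved in opposite directions in the progenitor-like cells of the Lin- and the Lin+ libraries, and the difference between fractions was not tested. The adipocyte-abundant list was at 0.31 in Lin- and -0.58 in Lin+, the committed preadipocyte list at 0.082 and -0.69, the extracellular matrix list at 0.10 and -0.15, and the oxidative phosphorylation list at 0.058 and -0.19. In Lin- the direction turned with the setting for 2 of them, as the median log2 of adipocyte abundant list, fibroblast or adipose progenitor-like, Lin-, was -0.17 for members with at least 100 UMIs (0.052 without the top cells), and the median log2 of oxidative phosphorylation list, fibroblast or adipose progenitor-like, Lin-, -0.022 with scaled cells. TMM scaling, which moved every gene of the class by -0.062, put the latter at -0.0046. Cells of unnamed clusters led by haemoglobin genes, which have no class name, made up 12.2% (11.2 to 13.2) of the Lin+ iAdFASNKO library and 6.93% (6.03 to 7.91) of the Lin+ control library.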

How the results depend on the processing

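The alternatives without B- and T-cell-like cells, with haemoglobin-led myeloid cells, without the highest cell of each gene, with M1 alone and with marker classes for the proliferating share were tests chosen after seeing the data. Over all alternatives 107 of 140 class shares, 332 of 452 list medians, 496 of 615 named genes and 8 of 8 proliferating shares stayed within the counting interval of the reported value. Another 32, 79 and 111 moved beyond it and 1, 41 and 8 reversed. A value counted as reversed only where the reported interval left out no difference. Otherwise a turn beyond the interval counted as moved, as for the thermogenic list of progenitor-like cells (0.08 in Lin-, -0.37 in Lin+). Named genes other than Fasn could not reverse in the other fraction, since they were chosen to lie on the same side of 1 there. The ratio of macrophage-like shares, Lin+, was 0.458 with the looser and 0.760 with the stricter filter, 0.393 with genotypes clustered separately, 0.174 among immune cells and 0.434 without B and T cells. The ratio of B cell-like shares, Lin+, was 3.48 (stricter) and 1.65 (immune cells), and the ratio of T cell-like shares, Lin+, 1.48 (immune cells), where the denominator is the cause. The ratio of fibroblast or adipose progenitor-like shares, Lin-, was 0.801 (looser), 0.875 (stricter) and 0.765 (stromal cells). The ratio of fibroblast or adipose progenitor-like shares, Lin+, was 0.595 (looser), 0.925 (stricter), 0.646 (resolution 0.5), 0.809 (separate clustering), 0.634 (markers), 0.962 (stromal cells) and 0.836 (without B and T cells). The ratio of pericyte or smooth muscle-like shares, Lin-, was 1.30 (looser) and 6.50 (stricter), and the ratio of endothelial-like shares, Lin-, 0.473 (separate clustering). The ratio of immune shares, Lin+ over Lin-, control, was 6.49 (stricter), and the ratio of immune shares, Lin+ over Lin-, iAdFASNKO, 11.9 (stricter) and 8.11 (markers per cell). In macrophage-like cells the median log2 of alternative macrophage activation list, macrophage-like, Lin+, was -0.031 (looser), -0.018 (without the top cell) and -0.031 (M1). The median log2 of classical macrophage activation list, macrophage-like, Lin+, was -0.19 (looser), -0.078 (M1) and -0.23 (no UMI minimum). The median log2 of lipid-associated macrophage list, macrophage-like, Lin+, was -0.28 (looser), -0.18 (stricter), -0.53 (markers), -0.45 (scaled cells) and -0.18 (M1). The median log2 of proliferation list, macrophage-like, Lin+, was 0.57 (stricter), 0.078 (without the top cell), 0.017 (no minimum) and 0.13 (at least 100 UMIs). The median log2 of MHC class II list, macrophage-like, Lin+, was 0.0038 (scaled cells), and the median log2 of oxidative phosphorylation list, macrophage-like, Lin+, -0.20 (markers), and the median log2 of extracellular matrix list, macrophage-like, Lin+, was 0.39 (markers) and 0.088 (scaled cells), and the committed list was at 0.19 (looser), 0.21 (stricter) and 0.056 (M1). Log2 ratios were -1.54 (markers) and -0.50 (without the top cell) for Arg1, and 0.88 (looser) and 1.04 (M1) for Fabp5. In Lin- progenitor-like cells the adipocyte abundant list was at -0.58 (other fraction) and -0.17 (at least 100 UMIs), the interstitial list at 0.72 and the committed list at -0.69 in the other fraction. The CD142 list was at 0.023 (scaled cells) and 0.027 (other fraction), the matrix list at -0.15 (other fraction), the chemokine list at -0.50 (TMM) and 0.048 (other fraction), and the oxidative phosphorylation list at -0.0046 (TMM), -0.022 (scaled cells) and -0.19 (other fraction). The log2 ratio of Col3a1, T cell-like, Lin+, was -3.62 (stricter), -0.25 (doublets kept) and -1.72 (markers). In T-cell-like cells the median log2 of extracellular matrix list, T cell-like, Lin+, was -0.32 (looser), -2.26 (stricter), -0.42 (doublets kept), -1.70 (markers) and -0.069 (scaled cells), the median log2 of committed preadipocyte list, T cell-like, Lin+, -0.42, -2.28, -0.57 and -1.29 in the first 4 of these and -0.12 without the top cell, and the median log2 of interstitial progenitor list, T cell-like, Lin+, -0.32 (doublets kept). In B-cell-like cells the interferon list was at -0.086, Sparc at 0.094, the matrix list at 0.31 and the committed list at 0.91 (stricter). In endothelial-like cells the matrix list was at -0.27 (doublets kept). In smooth muscle-like cells the matrix list was at 0.045 (looser) and 0.29 (stricter). Elsewhere the cause was not tested. Stricter filtering and separate clustering each gave 13 of 15 shares, as no cluster took the other names. No paired analysis was possible because each group is 1 library, no test was run and the labels share only replicate number 1. Depth was low in macrophage-like cells, with 333417 UMIs in iAdFASNKO, and in ILC2-like cells, with 318238.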

Other observations

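The values within ILC2-like cells were chosen only after their shares had been seen, and no tests were run on them. These cells numbered 94 and 193, under the minimum of 100 set for comparing a class.

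In Lin-, ILC2-like cells, a source of type 2 cytokines in fat, were at 3.06% of control and 4.47% of iAdFASNKO cells, a ratio of 1.46 (1.15 to 1.86). Their type 2 immunity list was at -0.29 (-0.58 to 0.25), with 1 of 9 higher and 2 lower. The interleukin-33 receptor Il1rl1 was at 0.586 (0.461 to 0.741), Il2ra at 0.632 and Gata3 at 0.725 (0.580 to 0.903), while the interleukin-25 receptor subunit Il17rb was at 2.75 (1.57 to 5.03) and Il13, at 1.5 (0.819 to 2.79), was not told apart with all cells and was at 2.87 (1.30 to 6.99) without the top cells. The stress list was at -0.68 (-0.77 to -0.57), with 1 of 17 higher and 12 lower, such as Fos at 0.424. The MHC class II list was at 0.94, with 3 of 5 higher, among them Cd74 at 1.76 (1.33 to 2.35), of which 1 control cell held 55 of 81 UMIs. Without the top cells the list was at 2.28, with 5 of 5 higher, and Cd74 at 4.85 (3.15 to 7.72). The extracellular matrix list, of stromal transcripts, was at 0.75 (0.34 to 1.18) in the same cells, with 4 of 7 higher and 0 lower, such as Col1a2 at 4.37 (2.36 to 8.72), in a library that also held more migratory dendritic-like cells (5 and 40). In the other cells of these libraries Cd74 was at 0.883, H2-Aa at 0.610, H2-Ab1 at 0.653 and H2-Eb1 at 0.763, whereas Ctss was at 1.89. The source of the MHC class II transcripts was not tested. Median depths were 3534 and 1573 UMIs per cell.

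Schwann-like cells were at 2.64% and 4.71% of Lin-, a ratio of 1.79 (1.39 to 2.30), and migratory dendritic-like cells at 0.163% and 0.927%, or 5 and 40 cells, a ratio of 5.70 (2.25 to 14.4). Epithelial-like cells were at 1.14% and 0.371%, a ratio of 0.326 (0.181 to 0.588). NK-like cells of Lin- were at 1.24% and 0.742%, a ratio of 0.600 (0.376 to 0.958), the same side of 1 as in Lin+. Monocyte-like cells numbered 1 in the Lin+ control and 18 in the Lin+ iAdFASNKO library, a ratio of 11.8 (1.58 to 88.5). T-cell-like cells of Lin- numbered 7 and 42. A cluster led by proliferation genes, unnamed, held 1.04% and 0.636% of Lin+ and 0.358% and 0.881% of Lin- cells. In progenitor-like cells of Lin+, the naive lymphocyte list was at 1.51 and the MHC class II list at 0.62, in the library that also held more B-cell-like cells. The B-cell transcript Cd79a was seen in 1.52% and 5.97% of these cells, at median depths of 8526 and 6817 UMIs, beside 0.99% and 4.63% of T-cell-like cells at 3002 and 3739 UMIs.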
